A study of Homo sapiens with 10 samples.

How the data were processed

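RNA sequencing was analysed for 10 samples of IMR90 cells, an established human fetal lung fibroblast line, in 5 groups of 2 samples. Groups were taken from the sample titles. They are control cells, senescent cells with a control knockout (senescent control), senescent cells with METTL3 knockout, and senescent METTL3 knockout cells with a wild type or a mutant METTL3 knock-in. Per the labels' protocols, cells were infected with a retrovirus that was empty or expressed RAS, transfected with siRNA and infected with a lentivirus carrying a wild type or mutant gene. The protocol text of these samples names METTL14 as the gene, while the titles name METTL3 and the column names of the count table give an siRNA against METTL3. The column names of the knockout samples also hold the word vec, and those of senescent control do not. Whether the cells of either group received an empty lentivirus is not given in the sources used here. Comparisons of senescent control with the knockout and the knock-ins may therefore also reflect a lentivirus. The same holds for the knock-ins against the knockout, if the knockout cells received none. The word knockout is used below as the titles use it, for what the protocol describes as siRNA. Which METTL3 mutant was used is not given in the sources used here. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

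Per the labels' protocols, total RNA was extracted with the RNeasy kit, digested with DNase I and made into libraries with the KAPA RNA HyperPrep kit. Per the submitters' processing notes, Bowtie2 (version not given) and RSEM 1.2.12 were used with the genome build hg19. The authors deposited 1 table of whole-number read counts per Ensembl gene, with no normalization. The annotation, the strand setting of the counting, the treatment of reads that map to several genes and any filter are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical genes such as HSPA1A and HSPA1B, the KRTAP genes and the histone genes, may therefore be divided in ways that cannot be checked, and values of these genes are uncertain. No coordinates are printed, because the reference annotation used here belongs to another build than the authors' values.

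The table held 57736 gene IDs, of which 39501 had a symbol in the symbol table used here and 52301 had a gene type in the reference annotation. Total counts per sample ran from 16293975 to 23570266. METTL3 alone took 5.87% and 5.86% of the counts of the wild type knock-in samples and 11.3% and 14.2% of those of the mutant knock-in samples, against 0.00791% or less in the other samples. Intervals and floors given for counts cover counting error only, since the reads carry no molecular identifiers in the sources used here.

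Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 16760 genes, and libraries were scaled by TMM. One model with a coefficient per group was fitted to all 10 samples (5 residual degrees of freedom), and groups were compared with the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison. The words rose, fell, higher and lower below, used of a gene in a comparison, mean an adjusted p under 0.05 in this test unless a value is given without them. Log2 fold changes are followed by a standard error (SE), computed from the fold change and its F statistic. The F statistic uses a dispersion estimated over all 10 samples. An SE therefore does not measure the spread of the 2 compared groups alone. CPM values, counts scaled to a common library total, were computed from the deposited counts and the TMM-scaled totals, as mean ± SD with n = 2. With a median common biological coefficient of variation of 9.22%, simulated counts with the means and library sizes of the real samples were tested in the same way, with 200 genes changed by known folds. For METTL3 knockout against senescent control, 84% of the genes changed 2-fold and 95% of those changed 4-fold were called, with 17 false calls among 16220 genes. For mutant against wild type knock-in the shares were 85% and 96%, with 14 false calls among 16180 genes. With 200 changed genes, false calls made up more than 0.05 of all calls in both runs. The simulation gave each gene its mean over all 10 samples and the same dispersion in every group. It therefore lacks any wider spread of a single group.

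Before the data were examined, 22 gene lists were fixed from general knowledge. They cover the senescence-associated secretory phenotype (SASP, the set of secreted factors made by senescent cells; in 3 lists of cytokines, proteases and growth factors), NF-kB targets, interferon-stimulated genes, RAS-ERK output, p53 targets, S phase, G2 and M phase, extracellular matrix and contractile genes, the m6A machinery, cholesterol synthesis, the ATF4 response, endoplasmic reticulum (ER) chaperones, lysosome, immediate early and heat shock genes, histones, mitochondrially encoded genes, and markers of epithelial, endothelial, immune and smooth muscle cells. A joined list, SASP all, holds the 3 SASP lists. Some lists share genes, so their results are not independent. Among the shared genes are SESN2 (ATF4 response and p53), GDF15 and FAS (SASP and p53) and ICAM1 (SASP and NF-kB). Mitochondrially encoded genes are not analysed here. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over all lists and comparisons, and again with a correlation estimated from the samples. A list p printed below is the preset one unless an estimated correlation is named.

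Genes to be named were also fixed by rule before the data were examined: 6 genes that check the labels (METTL3, METTL14, HRAS, CDKN1A, CDKN2A, LMNB1), a SASP panel of 10 genes, the 5 largest rises and 5 largest falls of each comparison among protein-coding genes with a mean of at least 5 CPM and no overlap between the groups' samples, and up to 4 members of each list with the smallest p. Where a group had no counts of a gene, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of counts is given with its 95% interval. Largest rises and largest falls below are those among genes that met the naming rule, and other genes can change by more.

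The alternatives tried were other scalings (DESeq2 size factors as RLE, upper quartile), the DESeq2 1.42.0 Wald test, no filter and a stricter filter (1 CPM in 2 samples), a fit of only the 2 groups compared, the replicate number as a block, each sample left out in turn, a threshold of 0.01 on the adjusted p, a log2 fold change of at least 1, and for lists the estimated correlation and the rotation test fry. After the data were seen, a run with METTL3 removed from the counts and totals and a run with the senescent samples alone were added.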

Results

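RNA was sequenced from IMR90 fibroblasts to compare growing cells with cells made senescent by RAS, an oncogene that drives fibroblasts into a stable arrest, and to ask what the loss and the return of METTL3 do to the senescent cells. METTL3 is the catalytic subunit of the complex that writes m6A, a methyl mark on RNA. The 5 groups held 2 samples each, with 16293975 to 23570266 counts per sample.

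The targeted gene was measured in every group. METTL3 (ENSG00000165819) stood at 77.1 CPM ± 6.2 (SD, n = 2) in control cells and 52.3 ± 7.09 in senescent control cells. It fell to 26.1 CPM ± 4.02 in the METTL3 knockout, a log2 change of -1.01 (SE 0.15) against senescent control, so METTL3 RNA was lowered and not absent. In the wild type knock-in it reached 58250 CPM ± 184, which is 756 times the control level, and in the mutant knock-in 130900 ± 23800. METTL14, the partner of METTL3 that the protocol text names, passed the test in none of the 5 main comparisons (edgeR quasi-likelihood adjusted p from 0.408 to 0.935), with group means from 23.9 to 30.7 CPM. HRAS (ENSG00000174775) rose from 14.7 CPM ± 0.105 in control to 61.2 ± 0.201 in senescent control cells. It was lower in the METTL3 knockout (40.2 CPM ± 0.905) and in the mutant knock-in (26.7 ± 4.29), and stood at 46.1 ± 3.77 in the wild type knock-in. The fall of METTL3 from control to senescent control (-0.56, SE 0.15) depended on single samples: edgeR's adjusted p was 0.00861 with all samples, 0.0588 without control sample 1, 0.135 without control sample 2 and 0.114 without senescent control sample 1 (range over its alternatives 6.96e-09 to 0.135).

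**Figure D1:**
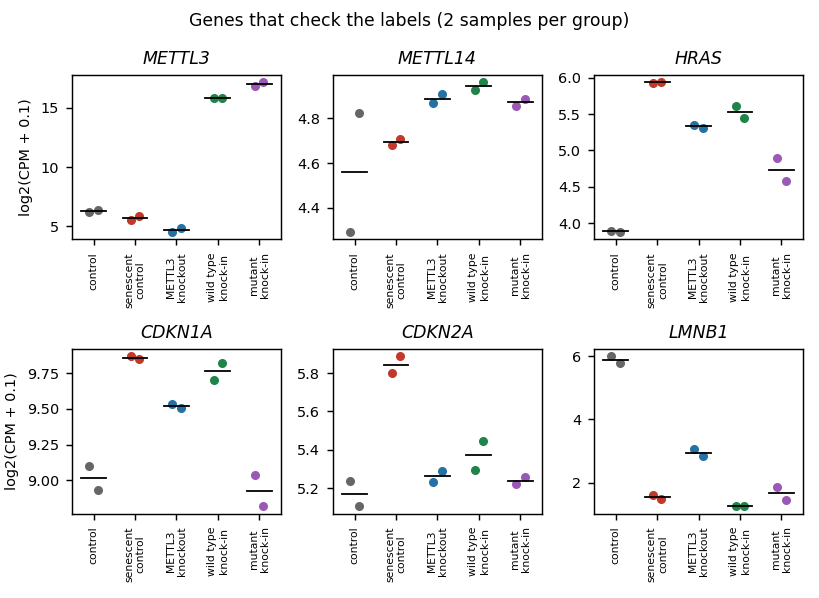
Each panel plots 1 gene as log2(CPM + 0.1) for the 5 groups; points are the 2 samples of a group and the black line is their mean on that scale. METTL3 lies between 26.1 and 77.1 CPM in the groups without a knock-in and at 58250 and 130900 CPM in the knock-ins.

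Senescent control cells were compared with control cells to describe the senescent state. IL1B, an alarm cytokine, rose by 9.60 on the log2 scale (SE 0.28), from 0.177 to 142.6 CPM. The neutrophil attractant CXCL8 rose by 8.20 (SE 0.19), to 249.5 CPM. The collagenase MMP1 rose by 4.55 (SE 0.11) to 3070 CPM, and the stromelysin MMP3 by 5.61 (SE 0.13). Cell division genes fell together, with 51 of 53 G2 and M phase genes and 40 of 41 S phase genes lower. LMNB1, the nuclear lamina protein that senescent cells lose, fell by 4.40 (SE 0.15), and the cell cycle inhibitors CDKN1A and CDKN2A rose by 0.85 (SE 0.10) and 0.67 (SE 0.09).

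In all, 3309 genes rose and 4240 fell out of 16760, of which 1522 and 1187 changed by at least 1 on the log2 scale. Among genes that met the naming rule the largest rises were IL1A, IL1B, LCE1F, CXCL1 and TNFSF15. IL1A, LCE1F and CXCL1 had 1 count each over the control samples, and their count ratios were 1060 (95% interval 189 to 41800), 868 (155 to 34300) and 650 (116 to 25700). TNFSF15, a cytokine of the tumour necrosis factor family, rose by 8.63 (SE 0.18). CCL20 and CSF2 had 0 counts in control and were at least 42.4-fold and at least 25.1-fold higher. The largest falls were H3C12, CDKN2C, H1-3, LMNB1 and H2BC13, from -4.69 (SE 0.18) for H3C12 to -4.36 (SE 0.22) for H2BC13. CDKN2C, a cyclin-dependent kinase inhibitor, fell by 4.57 (SE 0.22), and the others apart from LMNB1 are histone genes.

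Of 61 SASP genes tested, 42 rose and 9 fell (43 and 10 adjusted over the list alone), with a median log2 change of 1.32 (camera adjusted p = 3.06e-43 on the edgeR fit, and adjusted p = 0.034 with an estimated correlation). Among 20 cytokines and chemokines 16 rose and 1 fell (16 and 2 adjusted over the list alone), with IL6 up by 2.89 (SE 0.19) and CCL2, a monocyte attractant, by 0.59 (SE 0.13). Of 14 proteases and regulators 10 rose and 3 fell, both over all genes and adjusted over the list alone, with the plasminogen activator PLAU up by 1.82 (SE 0.11) and the serpin SERPINB2 by 3.87 (SE 0.11); for this list edgeR's camera test gave adjusted p = 0.0888 with an estimated correlation. Growth factors and receptors rose in 16 of 27 cases and fell in 5 (17 and 5 adjusted over the list alone). STC1, a secreted glycoprotein hormone, went from 253.9 to 3741 CPM, and the epidermal growth factor receptor ligand EREG rose by 4.32 (SE 0.12). Beside these lists, 2 of 5 immune cell markers were higher and 0 lower (3 and 0 adjusted over the list alone), with a median of 2.09, or 1.29 with genes absent from control at their bound. Camera on the edgeR fit gave adjusted p = 0.2, and adjusted p = 0.337 with an estimated correlation. PTPRC, the leukocyte antigen CD45, went from 0 to 21 counts and was at least 7.88-fold higher, and LYZ, the lysozyme of myeloid cells, rose by 1.29 (SE 0.32). Genes with a count numbered 21764 and 22161 in the control samples and 22705 and 22844 in senescent control, and lincRNA genes took 1.29% and 1.73% against 2.54% and 2.34% of the counts without METTL3.

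NF-kB is the transcription factor behind many inflammatory genes, and 17 of its 20 targets rose while 0 fell, both over all genes and adjusted over the list alone, although the camera call on the edgeR fit was lost (adjusted p = 0.0585 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose by 4.15 (SE 0.22) and the adhesion molecule ICAM1 by 3.01 (SE 0.16). RAS-ERK output genes rose in 10 of 16 cases and fell in 2, over all genes and adjusted over the list alone (camera on the edgeR fit, adjusted p = 0.228 with an estimated correlation), with the ERK phosphatase DUSP6 up by 1.91 (SE 0.10). Of 26 p53 targets 12 rose and 6 fell on both counts, adjusted over the list alone included (adjusted p = 0.0751 with an estimated correlation, edgeR and camera). Their strongest riser was GDF15, a stress cytokine, at 2.78 (SE 0.14). The S phase and G2 and M phase counts were the same adjusted over the list alone, with 40 and 51 genes lower. The median of the G2 and M phase genes was -2.58 (camera on the edgeR fit, adjusted p = 0.0255 for each of these lists with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 2.99 (SE 0.11). CCNB1, the mitotic cyclin, fell by 2.55 (SE 0.10). Of 12 replication-dependent histone genes 11 fell and 1 rose on both counts, adjusted over the list alone included, with H1-5 down by 4.36 (SE 0.14). Matrix and contractile genes fell in 17 of 26 cases and rose in 1 (19 and 1 adjusted over the list alone); the edgeR and camera call was lost (adjusted p = 0.404 with an estimated correlation). The proteoglycan DCN fell by 2.39 (SE 0.12). Interferon-stimulated genes rose in 15 of 39 cases and fell in 7 on both counts, adjusted over the list alone included; camera on the edgeR fit gave adjusted p = 0.0243, 0.084 without control sample 1, 0.201 without control sample 2, and adjusted p = 0.64 with an estimated correlation (range over its alternatives 0.00552 to 0.64). The control samples differed from each other more than those of any other group, with a chi-square per gene of 34.4 against 5.07 to 7.17 in the other 4 groups.

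METTL3 knockout cells were compared with senescent control cells to ask what the loss of METTL3 does to the senescent state. These groups may also differ by an empty lentivirus, as given above. Inflammatory genes raised in senescence fell, among them CXCL8 by 4.57 on the log2 scale (SE 0.14), IL1B by 5.20 (SE 0.19), from 142.6 CPM ± 21.9 to 3.86 ± 0.73, and IL1A by 3.15 (SE 0.16). MMP3 fell by 3.21 (SE 0.11) and MMP1 by 2.43 (SE 0.10), yet MMP1 at 569.5 CPM ± 11.2 stayed above its control level of 131 ± 9.02. Cell division genes were higher, with LMNB1 up by 1.44 (SE 0.17) to 7.65 CPM ± 0.781, against 59.4 ± 5.86 in control cells.

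In the knockout 1202 genes rose and 1444 fell, of which 342 and 327 changed by at least 1 on the log2 scale. With upper-quartile scaling the larger part turned, with 1452 higher and 1204 lower. Among genes that met the naming rule CXCL1, a neutrophil attractant, fell the most (-6.42, SE 0.37). It was followed by IL1B, TNFSF15 (-5.11, SE 0.13), LCE1F (-4.92, SE 0.23) and CXCL8. IL6 fell by 2.39 (SE 0.19), CCL2 by 2.36 (SE 0.15), CCL20 by 4.62 (SE 0.53) and CSF2, a myeloid growth factor, by 3.30 (SE 0.56). The largest rises were B3GALT2, a galactosyltransferase (4.07, SE 0.25), the interferon-stimulated gene IFI44L (2.61, SE 0.30), the oxytocin receptor OXTR (2.60, SE 0.18), ANKRD1, a target of the YAP co-activator (2.48, SE 0.19), and the potassium channel KCNK6, which rose from 4.51 to 19.2 CPM.

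Of the 61 SASP genes 40 fell and 1 rose (42 and 4 adjusted over the list alone), with a median of -0.94 (camera on the edgeR fit, adjusted p = 1.8e-66, and adjusted p = 0.0255 with an estimated correlation). The cytokines and chemokines fell in 15 of 20 cases and rose in 0 on both counts, adjusted over the list alone included, with a median of -2.77. Proteases fell in 9 of 14 cases and rose in 1 (10 and 2 adjusted over the list alone; camera on the edgeR fit, adjusted p = 0.0751 with an estimated correlation), and growth factors fell in 16 of 27 and rose in 0 (17 and 2 adjusted over the list alone). EREG fell by 2.65 (SE 0.11), the bone morphogenetic protein BMP2 by 2.73 (SE 0.12) and the tissue plasminogen activator PLAT by 1.26 (SE 0.12). NF-kB targets fell in 16 of 20 cases and rose in 0 on both counts, adjusted over the list alone included (median -0.94). TNFAIP3, a feedback inhibitor of NF-kB, fell by 1.61 (SE 0.12) and ICAM1 by 1.86 (SE 0.15). RAS-ERK output genes fell in 8 of 16 cases and rose in 0 (9 and 0 adjusted over the list alone), with DUSP6 down by 0.89 (SE 0.10) beside the fall of HRAS by 0.61 (SE 0.11); the edgeR and camera call was lost (adjusted p = 0.251 with an estimated correlation).

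Division genes went the other way in the knockout. Of 53 G2 and M phase genes 40 rose and 1 fell (43 and 1 adjusted over the list alone), with a median of 1.06, and of 41 S phase genes 27 rose and 1 fell (34 and 1 adjusted over the list alone), with a median of 0.65. KIF2C, a kinesin of the mitotic spindle, rose by 1.44 (SE 0.15) and the replication licensing factor CDC6 by 0.94 (SE 0.11). Camera on the edgeR fit gave adjusted p = 0.0489 and 0.0446 for these lists with an estimated correlation. Histone genes rose in 6 of 12 cases and fell in 0 (7 and 0 adjusted over the list alone; edgeR and camera, adjusted p = 0.14 with an estimated correlation), with H1-3 up by 1.87 (SE 0.18). Matrix and contractile genes rose in 14 of 26 cases and fell in 1 (15 and 2 adjusted over the list alone), with the smooth muscle protein CNN1 up by 1.27 (SE 0.13) and ACTA2, smooth muscle actin, by 0.96 (SE 0.11). Interferon-stimulated genes rose in 19 of 39 cases and fell in 1 (22 and 2 adjusted over the list alone); the gene that fell over all genes was the chemokine CXCL10 (-2.52, SE 0.26). Both calls were lost on the edgeR fit (camera adjusted p = 0.319 for matrix and 0.28 for interferon genes, each an adjusted p with an estimated correlation). The p53 targets rose in 5 of 26 cases and fell in 4 (6 and 5 adjusted over the list alone), and CDKN2A fell by 0.58 (SE 0.09). CDKN1A fell by 0.34 (SE 0.10) at an edgeR adjusted p of 0.0326, which was 0.188 and 0.153 without senescent control samples 1 and 2, 0.156 and 0.205 without knockout samples 1 and 2, and 0.0603 with upper-quartile scaling (range over its alternatives 1.17e-05 to 0.205). The 2646 calls became 1198 and 1368 without senescent control samples 1 and 2 and 1244 and 1260 without knockout samples 1 and 2, and 5621 when only these 2 groups were fitted.

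**Figure D2:**
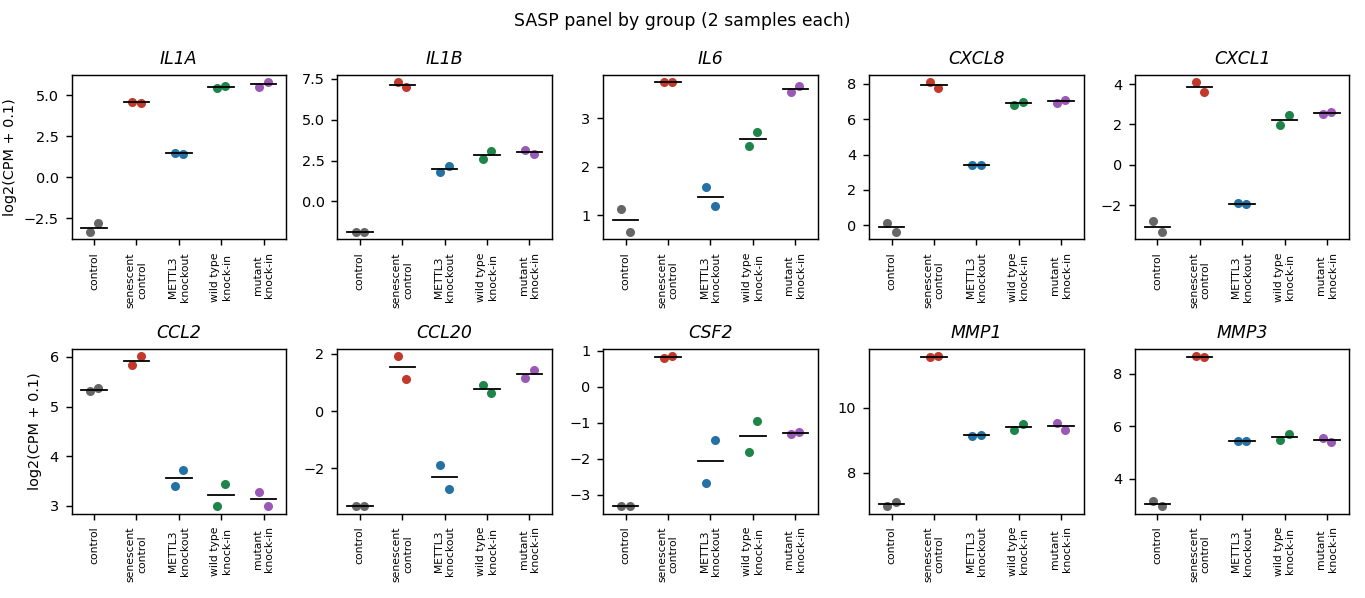
Each panel plots 1 gene of the SASP panel as log2(CPM + 0.1) for the 5 groups; points are the 2 samples of a group and the black line is their mean on that scale. IL1A, CXCL8 and CXCL1 fell in the knockout and rose in both knock-ins, while MMP3 stood at 43.6 CPM in the knockout and at 48.2 and 44.5 in the wild type and mutant knock-ins.

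The wild type knock-in was compared with the knockout to ask which genes change when METTL3 returns. Several neutrophil attractants and IL1A rose strongly: CXCL1 by 4.78 on the log2 scale (SE 0.42), IL1A by 4.09 (SE 0.15) and CXCL8 by 3.52 (SE 0.14). Other SASP genes did not pass the test, among them MMP3 (0.15, SE 0.10), MMP1 (0.26, SE 0.10), CCL2 (-0.33, SE 0.17) and CSF2 (0.91, SE 0.73). The stress gene HSPA6, an inducible heat shock protein, rose by 8.51 (SE 0.19) to 232.8 CPM ± 10.3, and ATF3, a transcription factor of the stress response, by 4.19 (SE 0.18). Division genes fell again, with 47 of 53 G2 and M phase genes lower.

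In total 3106 genes rose and 2478 fell, of which 1073 and 521 changed by at least 1 on the log2 scale. After METTL3 itself (11.12, SE 0.21) and HSPA6, the largest rises were EGR2, an immediate early transcription factor (5.83, SE 0.33), MYCT1 (5.79, SE 0.21) and ATF3. The largest falls were B3GALT2, which had risen in the knockout, the mitotic activator CDC20 (-2.81, SE 0.19), DLGAP5 (-2.55, SE 0.28), KIF20A (-2.54, SE 0.15) and GMNC (-2.51, SE 0.25). Of the 61 SASP genes 30 rose and 10 fell (32 and 11 adjusted over the list alone), with a median of 0.50; the camera call on the edgeR fit was lost (adjusted p = 0.208 with an estimated correlation). The cytokines and chemokines rose in 13 of 20 cases and fell in 1 on both counts, adjusted over the list alone included (camera on the edgeR fit, adjusted p = 0.0751 with an estimated correlation). IL6 rose by 1.22 (SE 0.20) and CCL20 by 3.79 (SE 0.58). IL1B rose by 0.91 (SE 0.22), with an edgeR adjusted p of 0.00694 that became 0.093 without knockout sample 1 and 0.115 without wild type sample 2 (range over its alternatives 6.85e-07 to 0.115). Proteases rose in 5 of 14 cases and fell in 3 (6 and 3 adjusted over the list alone), with SERPINB2 up by 1.25 (SE 0.10) and the metalloprotease inhibitor TIMP2 down by 1.04 (SE 0.13). Growth factors rose in 12 of 27 cases and fell in 6 (13 and 7 adjusted over the list alone), with GDF15 up by 1.67 (SE 0.13); camera on the edgeR fit gave adjusted p = 0.0195, 0.0782 without knockout sample 1, 0.111 without wild type sample 2, and adjusted p = 0.267 with an estimated correlation (range over its alternatives 0.00239 to 0.267).

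All 15 ATF4 response genes rose on both counts, adjusted over the list alone included (median 1.75; camera on the edgeR fit, adjusted p = 0.0307 with an estimated correlation), with ASNS, asparagine synthetase, up by 3.03 (SE 0.14) and the serine synthesis enzyme PSAT1 by 2.22 (SE 0.10). NF-kB targets rose in 19 of 20 cases and fell in 0, also adjusted over the list alone (median 1.54; the same adjusted p = 0.0307 with an estimated correlation), with TNFAIP3 up by 3.43 (SE 0.12) and the signalling adaptor TRAF1 by 3.42 (SE 0.15). Immediate early and heat shock genes rose in 10 of 15 cases and fell in 1 on both counts, adjusted over the list alone included (edgeR and camera, adjusted p = 0.0662 with an estimated correlation). HSPA1A rose by 3.90 (SE 0.11) and the immediate early factor EGR1 by 3.34 (SE 0.15). In the knockout against senescent control 5 of the 15 ATF4 genes had fallen and 0 risen, with a median of -0.30. Of the 15 immediate early and heat shock genes 3 had fallen and 1 risen there. Camera on the edgeR fit gave adjusted p = 0.0243 and 0.148 for these 2 lists, and 0.462 and 0.633 with an estimated correlation. Most single genes of these 2 lists that rose therefore had no fall called in the knockout. The ATF4 list as a whole was called lower there with the preset correlation, so part of its rise may undo a fall. Interferon-stimulated genes rose in 31 of 39 cases and fell in 0 (33 and 0 adjusted over the list alone; edgeR and camera, adjusted p = 0.2 with an estimated correlation), with the RNA sensor IFIH1 up by 2.15 (SE 0.17). Of 26 p53 targets 14 rose and 1 fell (15 and 1 adjusted over the list alone; edgeR and camera, adjusted p = 0.0451 with an estimated correlation), with SESN2 up by 1.63 (SE 0.10). SESN2 is also on the ATF4 list. The G2 and M phase genes, 47 lower and 2 higher on both counts, adjusted over the list alone included, had a median of -1.47, and CCNB1 fell by 1.46 (SE 0.10). S phase genes fell in 27 of 41 cases and rose in 1 (28 and 3 adjusted over the list alone; edgeR and camera, adjusted p = 0.0751 with an estimated correlation). Matrix and contractile genes fell in 16 of 26 cases and rose in 2 (17 and 2 adjusted over the list alone; edgeR and camera, adjusted p = 0.399 with an estimated correlation). The smooth muscle protein CNN1 fell, while POSTN, a matrix protein, rose by 1.28 (SE 0.12). RAS-ERK output genes rose in 4 of 16 cases and fell in 3 on both counts, adjusted over the list alone included. Immune cell markers were higher beside these lists, 3 of 5 and 0 lower, also adjusted over the list alone (edgeR and camera, adjusted p = 0.0751 with an estimated correlation). CD68, a lysosomal protein abundant in macrophages, rose by 1.03 (SE 0.09), and LCP1, an actin bundling protein of blood cells, went from 3 to 108 counts over the group, a ratio of 34.7 (95% interval 11.6 to 171). PTPRC was the third, from 8 to 44 counts, with an edgeR adjusted p of 0.0111 that was 0.0984 without knockout sample 1 and 0.0821 without wild type sample 1 (range over its alternatives 9.42e-05 to 0.0984). Beside these lists, genes with a count went from 22663 and 22713 in the knockout samples to 24270 and 24501 in the wild type knock-in. Of the counts without METTL3, lincRNA genes took 2.20% and 2.31% in the knockout and 3.40% and 2.62% in the wild type, and protein-coding genes 91.8% and 92.4% against 89.8% and 91.4%. The 5584 calls became 3390 and 3446 without knockout samples 1 and 2 and 3551 without wild type sample 1. METTL3 stood 756 times above its control level in these cells, so this comparison is of the knockout with a large excess of METTL3. It may also reflect a lentivirus, as given above.

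The mutant knock-in was compared with the knockout to ask the same of a mutant METTL3. These groups may also differ by a lentivirus, as given above. IL1A rose by 4.25 on the log2 scale (SE 0.15), CXCL8 by 3.63 (SE 0.14) and IL6 by 2.26 (SE 0.19). Interferon-stimulated genes rose nearly as a whole, 38 of 39, and the heat shock gene HSPA1A rose by 5.24 (SE 0.12) to 2963 CPM ± 290. ACTA2, smooth muscle actin, fell by 1.80 (SE 0.11).

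Here 4046 genes rose and 4073 fell (4382 and 3603 with upper-quartile scaling), of which 1856 and 672 changed by at least 1 on the log2 scale. The largest rises were METTL3 (12.29, SE 0.22), HSPA6 (9.82, SE 0.19), MYCT1 (6.75, SE 0.20), the lipoxygenase ALOXE3 (6.26, SE 0.32) and EGR2 (5.99, SE 0.33). The largest falls were KRTAP2-3 (-3.09, SE 0.24), GMNC (-2.70, SE 0.26), B3GALT2 (-2.68, SE 0.22), KRTAP1-5 (-2.64, SE 0.24) and the keratin KRT19 (-2.60, SE 0.25). Of the 61 SASP genes 29 rose and 14 fell (29 and 16 adjusted over the list alone), with a median of 0.32; the edgeR and camera call was lost (adjusted p = 0.279 with an estimated correlation). Cytokines and chemokines rose in 14 of 20 cases and fell in 3 on both counts, adjusted over the list alone included (edgeR and camera, adjusted p = 0.0707 with an estimated correlation), with CSF1, the macrophage growth factor, up by 1.83 (SE 0.12). CXCL1 rose by 5.10 (SE 0.42), CCL20 by 4.35 (SE 0.56) and IL1B by 1.03 (SE 0.22), while MMP3 (0.03, SE 0.11) and CSF2 (0.88, SE 0.75) did not pass the test. MMP1 rose by 0.28 (SE 0.10) and CCL2 fell by 0.44 (SE 0.17), with edgeR adjusted p of 0.0348 and 0.0474. For MMP1 this became 0.231 and 0.174 without knockout samples 1 and 2 and 0.317 and 0.0746 without mutant samples 1 and 2, and for CCL2 0.288 without knockout sample 2, 0.208 without mutant sample 2, 0.0518 and 0.0639 with RLE and upper-quartile scaling, 0.0541 with a stricter filter, 0.0509 with METTL3 removed and 0.058 with DESeq2 (ranges over their alternatives 0.000562 to 0.317 and 0.00328 to 0.288). Proteases rose in 4 of 14 cases and fell in 3 (4 and 5 adjusted over the list alone), and growth factors rose in 11 of 27 and fell in 8 on both counts, adjusted over the list alone included.

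The interferon-stimulated genes, 38 higher and 0 lower (39 and 0 adjusted over the list alone), had a median of 2.58 (camera on the edgeR fit, adjusted p = 0.0451 with an estimated correlation), with the antiviral GTPase MX2 up by 4.51 (SE 0.25) and IFIH1 by 3.90 (SE 0.17). NF-kB targets rose in 19 of 20 cases and fell in 0 (median 2.01) and ATF4 response genes in 15 of 15 (median 2.19), both unchanged adjusted over the list alone, and edgeR's camera adjusted p was 0.0307 and 0.034 with an estimated correlation. TNFAIP3 rose by 4.22 (SE 0.12), NFKB1 by 2.17 (SE 0.11) and TRIB3, a pseudokinase induced by ATF4, by 3.08 (SE 0.12). Immediate early and heat shock genes rose in 11 of 15 cases and fell in 1 on both counts, adjusted over the list alone included (edgeR and camera, adjusted p = 0.071 with an estimated correlation). Of 26 p53 targets 11 rose and 5 fell on both counts, adjusted over the list alone included (edgeR and camera, adjusted p = 0.0874 with an estimated correlation), with SESN2 up by 2.19 (SE 0.10) and CDKN1A down by 0.59 (SE 0.10). G2 and M phase genes fell in 41 of 53 cases and rose in 2 (42 and 2 adjusted over the list alone) and S phase genes fell in 23 of 41 and rose in 4 on both counts, adjusted over the list alone included, with edgeR and camera calls lost (adjusted p = 0.109 and 0.2 with an estimated correlation). CBX5, a heterochromatin protein on the G2 and M phase list, fell by 1.21 (SE 0.09) and RRM2 by 1.74 (SE 0.12). Matrix and contractile genes fell in 20 of 26 cases and rose in 2 on both counts, adjusted over the list alone included (edgeR and camera, adjusted p = 0.266 with an estimated correlation). Cholesterol synthesis genes fell in 19 of 25 cases and rose in 0 (21 and 0 adjusted over the list alone; edgeR and camera, adjusted p = 0.1 with an estimated correlation). Immune cell markers rose in 4 of 5 cases and fell in 0, also adjusted over the list alone (edgeR and camera, adjusted p = 0.0675 with an estimated correlation). CD68 rose by 1.12 (SE 0.09), PTPRC by 4.29 (SE 0.52), from 8 to 142 counts, and LCP1 from 3 to 141 counts, a ratio of 52.7 (95% interval 17.7 to 259). The fourth, CD163, was up by 1.39 (SE 0.46) with an edgeR adjusted p of 0.0265, which was 0.126 and 0.101 without knockout samples 1 and 2, 0.213 without mutant sample 2 and 0.0716 with DESeq2 (range over its alternatives 0.00202 to 0.213). Beside these lists, genes with a count numbered 25265 and 25582 in the mutant samples, lincRNA genes took 3.61% and 3.56% of the counts without METTL3, and protein-coding genes 89.2% and 89.3%. RAS-ERK output genes rose in 5 of 16 cases and fell in 5 on both counts, adjusted over the list alone included, with the cyclin CCND1 down by 0.87 (SE 0.09).

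**Figure D3:**
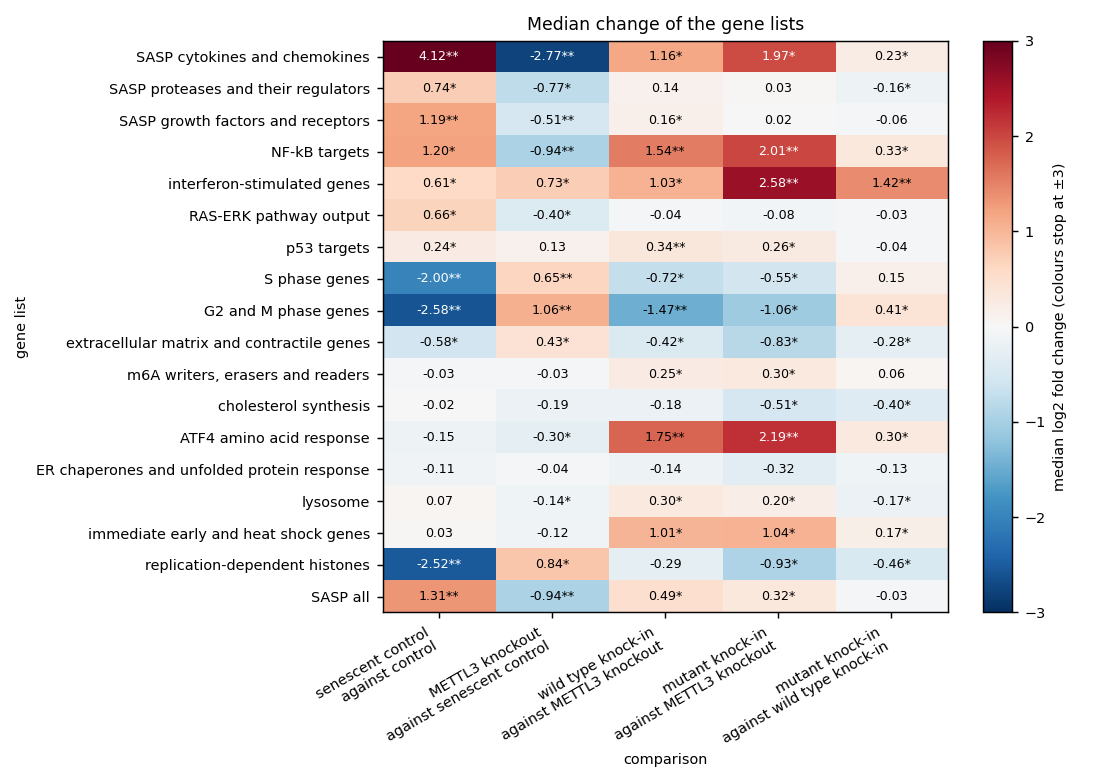
Rows are gene lists, columns are comparisons, and each cell gives the median log2 fold change of the tested members, with colours that stop at 3 on either side. One asterisk marks a camera adjusted p under 0.05 with the preset correlation and a pair of asterisks marks lists that also pass with an estimated correlation; interferon-stimulated genes read 1.03 for the wild type and 2.58 for the mutant knock-in against the knockout.

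The knock-ins were compared with each other to ask what the METTL3 mutation changes. Interferon-stimulated genes were higher in the mutant knock-in, 34 of 39, with MX2 up by 2.87 on the log2 scale (SE 0.21) and IFI44L by 2.52 (SE 0.21) to 121 CPM ± 6.98. The heat shock genes HSPA1A and DNAJB1 rose by 1.34 (SE 0.10) and 0.89 (SE 0.09). HRAS fell by 0.78 (SE 0.11) and CDKN1A by 0.84 (SE 0.10), and METTL3 itself rose by 1.17 (SE 0.14). The SASP panel genes IL1A (0.16, SE 0.11), IL1B (0.12, SE 0.20), CXCL8 (0.11, SE 0.12), CXCL1 (0.31, SE 0.23), MMP1 (0.02, SE 0.10) and MMP3 (-0.12, SE 0.11) did not pass the test.

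In the mutant 865 genes were higher and 1238 lower than in the wild type knock-in, of which 293 and 24 differed by at least 1 on the log2 scale. With upper-quartile scaling the larger part turned, with 1056 higher and 773 lower. The largest rises were MX2, OAS1 (2.64, SE 0.25), IFI44L, MX1 (2.41, SE 0.24), all antiviral genes, and the receptor ERBB4 (2.40, SE 0.24). Among the largest falls were ATXN7L3B (-1.28, SE 0.09) and the transporter SLC16A6 (-1.05, SE 0.11). The other largest falls, INMT (-1.08, SE 0.17), KRTAP2-3 (-0.97, SE 0.27) and a gene without a symbol, ENSG00000256500 (-1.03, SE 0.27), depended on single samples. For INMT the edgeR adjusted p was 0.0602 without mutant sample 2 (range over its alternatives 5.57e-10 to 0.0602). For KRTAP2-3 it was 0.333 without wild type sample 2, 0.129 without mutant sample 1 and 0.224 without mutant sample 2, and for ENSG00000256500 0.306, 0.171 and 0.0639 in the same order (ranges over their alternatives 1.09e-06 to 0.333 and 4.8e-09 to 0.306). IL6 was higher by 1.04 (SE 0.17), at 12.2 CPM ± 0.733 against 5.86 ± 0.873, with an edgeR adjusted p of 0.00435 that was 0.0777 without mutant sample 2 (range over its alternatives 1.49e-06 to 0.0777). The interferon list (34 higher and 0 lower, 36 and 0 adjusted over the list alone) had a median of 1.42 (camera on the edgeR fit, adjusted p = 0.034 with an estimated correlation), and its median stayed between 1.24 and 1.53 when each sample was left out. Beside it, genes with a count numbered 25265 and 25582 in the mutant and 24270 and 24501 in the wild type samples, and 1 of 5 immune cell markers was higher and 0 lower, also adjusted over the list alone (edgeR and camera, adjusted p = 0.177 with an estimated correlation). That marker was PTPRC, at 1.89 (SE 0.40), with an edgeR adjusted p of 0.0138 that was 0.156 without wild type sample 2 and 0.192 without mutant sample 2 (range over its alternatives 1.03e-05 to 0.192). EPSTI1 rose by 1.95 (SE 0.15), IFIH1 by 1.76 (SE 0.14) and HERC5, a ligase for the ubiquitin-like ISG15, by 2.13 (SE 0.20).

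Among the 61 SASP genes 5 were higher and 7 lower (6 and 8 adjusted over the list alone), with a median of -0.03 (edgeR and camera, adjusted p = 0.821, and adjusted p = 0.95 with an estimated correlation). PLAU fell by 0.79 (SE 0.10) and STC1 by 0.75 (SE 0.09). Cytokines and chemokines were higher in 4 of 20 cases and lower in 0, proteases higher in 1 of 14 and lower in 4, both counts the same adjusted over the list alone, and growth factors higher in 0 of 27 and lower in 3 (1 and 4 adjusted over the list alone). The camera call of the cytokines on the edgeR fit was lost without wild type sample 1 (adjusted p = 0.141), that of the proteases without wild type sample 2 (0.192) and without mutant sample 2 (0.0785), and both with an estimated correlation (adjusted p = 0.275 and 0.503). NF-kB targets were higher in 6 of 20 cases and lower in 0 (10 and 0 adjusted over the list alone), with TNFAIP3 up by 0.80 (SE 0.10). Immediate early and heat shock genes were higher in 4 of 15 cases and lower in 0 on both counts, adjusted over the list alone included. Cholesterol synthesis genes were lower in 12 of 25 cases and higher in 0 (20 lower adjusted over the list alone), and matrix and contractile genes lower in 9 of 26 and higher in 0 (12 lower adjusted over the list alone). G2 and M phase genes were higher in 10 of 53 cases and lower in 1 (11 and 1 adjusted over the list alone), ATF4 response genes higher in 4 of 15 and lower in 0 (7 and 0 adjusted over the list alone). For these 6 lists the camera call on the edgeR fit was lost, with adjusted p = 0.162, 0.252, 0.0662, 0.298, 0.228 and 0.242 with an estimated correlation, in the order given. S phase genes were higher in 7 of 41 cases and lower in 2 (9 and 2 adjusted over the list alone), p53 targets higher in 1 of 26 and lower in 1, and RAS-ERK output genes higher in 1 of 16 and lower in 0, the last 2 lists with the same counts adjusted over the list alone. The number of calls depended on single samples: 2103 became 1178 and 152 without wild type samples 1 and 2, and 680 and 123 without mutant samples 1 and 2.

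The knock-ins were also set against senescent control cells to measure how far SASP genes returned. IL1A was above its senescent control level in both knock-ins, by 0.94 (SE 0.12) in the wild type and 1.10 in the mutant, while IL1B changed by -4.28 (SE 0.17) in the wild type and -4.16 in the mutant. In the wild type knock-in MMP3 changed by -3.06 (SE 0.11) and CSF3, a granulocyte growth factor, by -3.95 (SE 0.26). Of 20 NF-kB targets 11 were higher and 5 lower in the wild type (12 and 5 adjusted over the list alone). In the mutant 13 were higher and 1 lower (13 and 2 adjusted over the list alone). Camera on the edgeR fit gave adjusted p = 0.193 and 0.115 with an estimated correlation. TRAF1 was up by 3.27 (SE 0.15) in the wild type. ATF4 response genes were higher in 13 of 15 cases in the wild type and 14 in the mutant, with 0 lower. Their medians were 1.60 and 1.99, and camera on the edgeR fit gave adjusted p = 0.0413 and 0.0451 with an estimated correlation. Of 15 immediate early and heat shock genes 7 were higher and 2 lower in the wild type, and 9 and 2 in the mutant. Here camera gave adjusted p = 0.0938 and 0.0991 with an estimated correlation. Of 39 interferon-stimulated genes 34 were higher and 1 lower in the wild type and 38 higher and 0 lower in the mutant, also adjusted over the list alone (edgeR and camera, adjusted p = 0.0938 and 0.0451 with an estimated correlation). Beside them, 2 of 5 immune cell markers were higher in the wild type and 4 in the mutant, with 0 lower (3 and 4 higher adjusted over the list alone; edgeR and camera, adjusted p = 0.0824 and 0.0739 with an estimated correlation).

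Of 42 SASP genes that rose in senescence, 36 fell in the knockout. Of these 36, 22 were higher in the wild type knock-in than in the knockout and 21 in the mutant knock-in, 19 of them in both. The 36 were picked for low values in the same knockout samples, which favours a rise against them. Over all genes, 475 of the 1444 that fell in the knockout were higher in the wild type knock-in and 468 in the mutant knock-in. In the wild type 3 of the 36 were lower than in the knockout and in the mutant 5, and these were named after their values were seen. Against the knockout, PLAT changed by -0.84 (SE 0.12) in the wild type and -0.97 (SE 0.12) in the mutant, the decoy receptor TNFRSF11B by -0.52 (SE 0.11) and -0.67 (SE 0.11), and the cytokine IL11 by -0.71 (SE 0.16) and -0.56 (SE 0.16). The others in the mutant were CCL2, given above, and the growth factor HGF (-0.38, SE 0.12). In the mutant the edgeR adjusted p of IL11 was 0.0723 without mutant sample 2, and that of HGF 0.0556 and 0.0931 without knockout samples 1 and 2 and 0.11 without mutant sample 2 (ranges over their alternatives 0.00167 to 0.0723 and 2.21e-05 to 0.11). Against senescent control, 25 of the 36 were still lower in the wild type and 25 in the mutant, and 2 and 3 were higher. Between the knock-ins, 2 of the 36 were higher and 7 lower in the mutant. Over the 42 genes the median log2 difference to senescent control was -1.58 in the knockout, -0.97 in the wild type knock-in and -0.92 in the mutant knock-in, and the median difference of mutant and wild type was -0.03 (quartiles -0.23 and 0.20). That last median was 0.13 without wild type sample 2. Against senescent control, 3482 genes rose and 3197 fell in the wild type knock-in, and 4529 rose and 4410 fell in the mutant. With upper-quartile scaling these splits were 3861 and 2829 in the wild type and 5228 and 3698 in the mutant, and with DESeq2 the larger part turned, to 2733 and 2832 and to 3756 and 3957. The wild type count of 6679 became 4367 without senescent control sample 2. The SASP list as a whole was lower than in senescent control, 33 genes lower and 10 higher in the wild type (35 and 11 adjusted over the list alone; edgeR and camera, adjusted p = 0.0849 with an estimated correlation) and 35 lower and 12 higher in the mutant (37 and 13 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation).

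**Figure D4:**
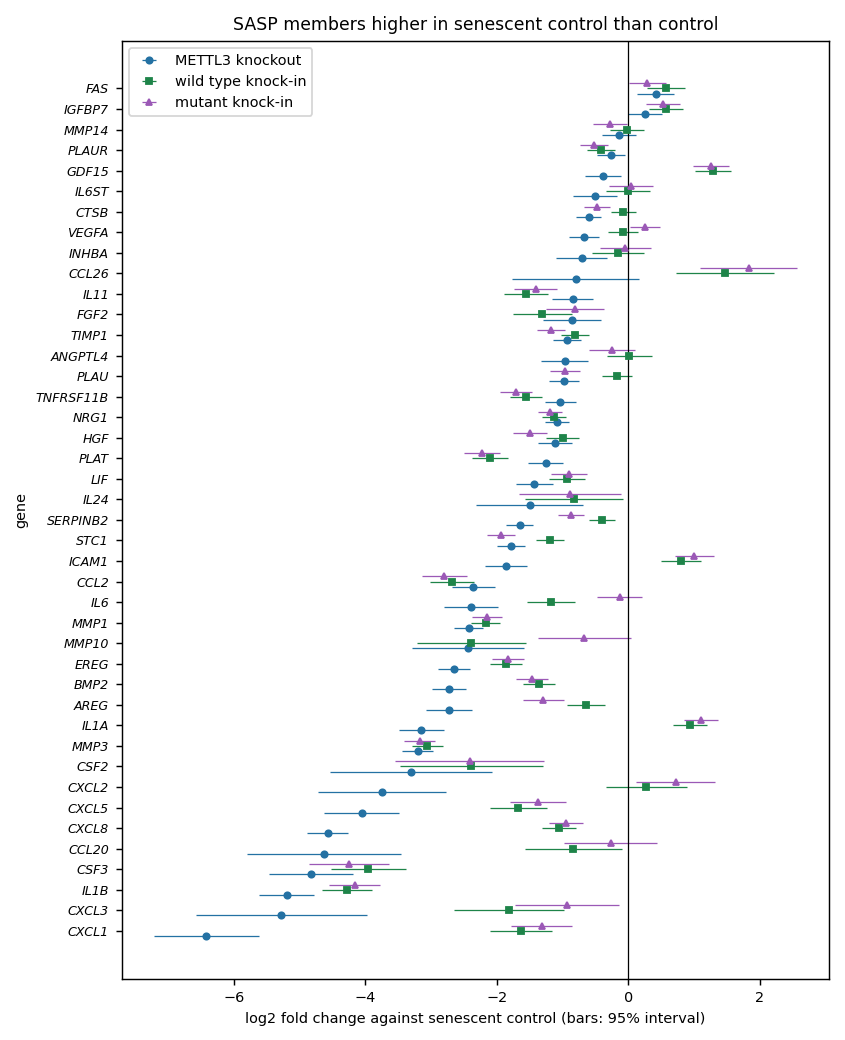
Each line is 1 of the 42 SASP genes that rose in senescence; the horizontal axis is its log2 fold change against senescent control in the knockout (circles), the wild type knock-in (squares) and the mutant knock-in (triangles), with 95% intervals. Medians over the genes are -1.58, -0.97 and -0.92; IL1A lies to the right of 0 in both knock-ins and IL1B near -4 in both.

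Senescence changes were set against the difference of knockout and knock-in, in comparisons that share no sample. METTL3 was in large excess in the knock-ins. These comparisons therefore cannot tell genes that move back with lower METTL3 from genes that respond to its excess. Across 16760 genes, which are not independent replicates, the log2 change of senescence correlated with the difference of knockout and wild type knock-in at r = -0.25, and with the difference of knockout and mutant knock-in at r = -0.26, against 0.010 and 0.009 in simulated unchanged groups. Genes that fell in senescence and were higher in the knockout than in the wild type knock-in numbered 1122, against 626.9 for independent lists, and those that rose and were lower numbered 774, against 613.2. With senescent control as a shared group, the correlation of senescence and knockout changes was -0.461 against -0.497 in the simulation (covariance -0.329 against -0.051). There 719 genes rose in senescence and fell in the knockout, against 285.1 for independent lists. The simulation gave a mean of 0.1 shared calls over all directions. Its groups are unchanged, so it cannot show the overlap that a shared group adds where genes do change. The changes of the knock-ins against the knockout, which share the knockout samples, correlated at 0.876 against 0.492 in the simulation (covariance 0.901 against 0.053), with 2588 genes up in both against 749.8 and 2118 down in both against 602.2 for independent lists. The simulation again gave 0.1 shared calls over all directions, with the same limit. A split would leave 1 shared sample in each part, so none was made, and part of the excess may come from the shared samples.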

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

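Of the tests below, the one of background reads behind the interferon-stimulated genes was fixed before its result was seen; the other 7, and the counts over all tested members of a list, were chosen after the result they bear on was seen. The change from the knockout differed between the wild type and the mutant knock-in for 2103 genes by a test of the difference itself, which is the comparison of the knock-ins, and this count was 123 without mutant sample 2 and 1178 without wild type sample 1. Among the genes named by rule, METTL3 differed by 1.168 on the log2 scale, HRAS by -0.783, CDKN1A by -0.836 and IL6 by 1.04. The interferon-stimulated genes differed by a median of 1.417. Outside the gene comparisons, reads over 808 olfactory receptor genes, which fibroblasts are not known to use, stood at 40.3 CPM of the counts without METTL3 in the mutant knock-in and 31.6 in the wild type knock-in, against 15.8 in control cells, 22.2 in senescent control and 23.0 in the knockout.

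In both knock-ins, 75 of 89 tested members of the ATF4, NF-kB, interferon and immediate early and heat shock lists were higher than in the knockout. Background reads over silent genes were set against the mean rise of an olfactory receptor gene. In each knock-in 100% of the risen members rose by over 20 times that rise. This share decides little, since the bar is low for genes already called higher. Over all 89 members, called or not, the difference in CPM exceeded that multiple for 86 in the wild type and 85 in the mutant. The median rises of all 89 were 15.2 and 38 CPM, against 0.0107 and 0.0214 for an olfactory receptor gene. These values argue against background of that size as the whole cause. Gene length was not taken into account. METTL3 reads taking part of the libraries are argued against as the whole cause, since they move all other genes alike, while the median of the 89 members, whose lists were taken up because they rose, lay 2.267 above that of all other genes in the mutant and 1.237 in the wild type, with lower quartiles of 1.24 and 0.722 above the other genes' upper quartiles of 0.5 and 0.361. This test replaced 2 that were run and seen and could not have decided, one taking METTL3 out of the counts and one giving the change of every other gene's share, -0.197 on the log2 scale, whose sign is fixed by arithmetic. The return of METTL3 cannot be told apart from its excess, because METTL3 in the wild type knock-in stood at 756 times the control level. Nor can METTL3 be told apart from the lentivirus that carried it, if the knockout cells received none.

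Of 39 interferon-stimulated genes, 34 were higher in the mutant than in the wild type knock-in. Of these genes 100% rose by over 20 times the mean rise of an olfactory receptor gene, with a median rise of 28.6 CPM. That share decides little, since the bar is low for genes already called higher. Over all 39 members, called or not, the difference exceeded that multiple in 39. The median difference of 22.1 CPM, against 0.0108 for an olfactory receptor gene, argues against background of that size. Gene length was not taken into account. The mutation cannot be told apart from the METTL3 level, which was 1.17 higher on the log2 scale in the mutant knock-in.

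Of 42 SASP genes raised in senescence, 36 fell in the knockout. If unarrested cells had diluted the senescent ones, other genes raised at least 4-fold in senescence would also have fallen. The 272 such genes had a median of -0.831 and an upper quartile of -0.138. The 36 genes, which were picked for having fallen, had a median of -2.11, and all 42 had -1.58. The lower quartile of the 272 genes, -1.647, lies below the latter. Dilution lowers a gene more the further it was raised, and the rises were not matched, so equal falls are not required. A broad partial fall therefore stays open. This test replaced one that had been run and seen, in which G2 and M phase genes implied a share of 18.7% unarrested cells and LMNB1 8.51%, where the SASP fall needed 76.8%. Lower HRAS RNA as the whole cause was set against the knock-ins. There HRAS differed by -0.783 and the 36 genes by a median of 0.022. This comparison cannot decide, because METTL3 also differed there by 1.168, and 6 of 20 NF-kB targets were higher in the mutant. RAS-ERK output genes fell in 8 of 16 cases in the knockout and in 0 of 16 between the knock-ins. Lower HRAS RNA and lower RAS signalling therefore stay open. Loss of METTL3 cannot be told apart from other effects of the knockout, since 22 of the 36 genes were higher again in the wild type knock-in and METTL3 was in excess there. Nor can it be told apart from an empty lentivirus, if the knockout cells received one and senescent control did not.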

How the results depend on the processing

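The runs with METTL3 removed and with the senescent samples alone were chosen after seeing the data; the other alternatives were planned. Where a value changed, the cause was not tested, except that stricter thresholds call fewer genes by construction. With an absolute log2 fold change of at least 1, the calls were 2709 for senescent control against control, 669 for knockout against senescent control, 1594 and 2528 for the wild type and mutant knock-in against the knockout, 317 between the knock-ins, and 1865 and 3056 for the wild type and mutant knock-in against senescent control. The share of higher genes between the knock-ins was then 92.4%, against 41.1% of all calls. At an adjusted p under 0.01 there were 1406 calls for knockout against senescent control, 3467 for wild type knock-in against knockout, 501 between the knock-ins and 4409 for wild type knock-in against senescent control. With only the 2 groups compared there were 5152 calls for senescence, against 7549 with all samples. For the knockout against senescent control there were 5621, and between the knock-ins 4078. With the senescent samples alone these last 2 were 4841 and 4968, against 2646 and 2103 with all samples. That run leaves out the control samples, whose chi-square per gene was 34.4, against 5.07 to 7.17 in the other groups. It gained 34 calls among the named genes and lost 1. Some genes that did not pass the test between senescent groups therefore passed there.

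With each sample left out in turn, where the lone sample of a group is assumed to vary like the other groups, calls ran from 5108 to 8974 for senescence, 1198 to 1368 for the knockout against senescent control, 3390 to 4150 and 5873 to 6652 for the wild type and mutant knock-in against the knockout, 123 to 1178 between the knock-ins, and 4367 to 5367 and 6864 to 7539 for the wild type and mutant knock-in against senescent control. Median differences of the SASP genes raised in senescence ran from -1.782 to -1.471 (knockout), -1.189 to -0.938 (wild type) and -1.162 to -0.817 (mutant) against senescent control, and from -0.129 to 0.13 between the knock-ins, where the sign turned without wild type sample 2. The correlation of the senescence change with knockout minus wild type ran from -0.247 to -0.177 and with knockout minus mutant from -0.254 to -0.19. NOTCH3 in senescence, at -0.03 with all samples, was 0.289 without control sample 1 (edgeR adjusted p 0.0275) and -0.23 without control sample 2.

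With an estimated correlation the SASP list lost its camera call in 4 comparisons with its median unchanged by construction: 0.495 (wild type against knockout), 0.318 (mutant against knockout), -0.646 and -0.814 (wild type and mutant against senescent control). Over the 154 tests of a list in a comparison, 70 calls were lost with an estimated correlation. Among the named genes 244 calls were lost and 6 gained over the runs that left out a sample. Sign changes among results called in neither setting (47 for genes, 25 for lists) are not counted as reversed. Other scalings moved the median of all genes by at most 0.096. The replicate numbers did not pair the samples: correlations of deviations over 10 pairs of groups ran from -0.12 to 0.061, with 0 over 0.1. With the replicate number as a block, calls were 7461 for senescence, 2538, 5473, 8019 and 1923 for the next 4 comparisons in the order above, and 6583 and 8860 against senescent control; 3 gene calls and 1 list call were lost and 2 gene calls gained.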

Other observations

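No test in this part is of a hypothesis. The list of the m6A machinery leaves out METTL3 itself. Of its 21 tested members 7 rose and 0 fell in the wild type knock-in against the knockout, also adjusted over the list alone. In the mutant 9 rose and 3 fell (10 and 3 adjusted over the list alone). YTHDC1, a nuclear m6A reader, rose by 0.97 (SE 0.11) and 1.27 (SE 0.11), YTHDF2, a reader that promotes RNA decay, by 0.72 (SE 0.09) and 0.90 (SE 0.09), and RBM15, a partner of the writer complex, by 0.95 (SE 0.09) and 0.82 (SE 0.09). On the edgeR fit camera gave adjusted p = 0.208 and 0.242 with an estimated correlation, 0.0533 for the former without wild type sample 2 and 0.0785 for the latter without mutant sample 2. In the knockout against senescent control 0 of the 21 passed edgeR's test on either count, adjusted over the list alone included.

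Lysosomal genes fell in the knockout in 6 of 23 cases and rose in 1 (11 and 1 adjusted over the list alone; edgeR and camera, adjusted p = 0.404 with an estimated correlation). The protease CTSL changed by -1.15 (SE 0.09) and the autophagy receptor SQSTM1 by -1.01 (SE 0.10). In the wild type knock-in against the knockout 13 rose and 0 fell (16 and 0 adjusted over the list alone). SQSTM1 rose by 1.68 (SE 0.10) there and the cholesterol transporter NPC1 by 1.04 (SE 0.09). In the mutant knock-in against the knockout 9 rose and 3 fell, also adjusted over the list alone. Between the knock-ins 0 were higher and 4 lower in the mutant (0 and 5 adjusted over the list alone). With an estimated correlation camera on the edgeR fit gave adjusted p = 0.302, 0.619 and 0.516 in this order. ER chaperone genes fell in 7 of 14 cases and rose in 2 in the mutant knock-in against the knockout, also adjusted over the list alone (edgeR and camera, adjusted p = 0.206, and 0.534 with an estimated correlation), and in 0 of 14 with 1 higher in the wild type, also adjusted over the list alone (adjusted p = 0.746 with an estimated correlation). In the mutant HSPA5, the main chaperone of the compartment, rose by 0.52 (SE 0.08), while the chaperone HYOU1 changed by -0.49 (SE 0.10). Histone genes fell in 8 of 12 cases and rose in 1 in the same comparison, also adjusted over the list alone (adjusted p = 0.275 with an estimated correlation), with H2BC21 at -1.15 (SE 0.10). In the wild type knock-in against the knockout 6 of the 12 were lower and 4 higher, also adjusted over the list alone, with a median of -0.29 (edgeR and camera, adjusted p = 0.0537, and 0.477 with an estimated correlation).

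Markers of other cell types were few, with 5 epithelial, 5 endothelial and 4 smooth muscle markers tested. KRT19, an epithelial keratin also found in cultured fibroblasts, changed by -2.80 (SE 0.21) in senescence, 1.78 (SE 0.22) in the knockout against senescent control and -2.60 (SE 0.25) in the mutant knock-in against the knockout. Among endothelial markers KDR rose by 2.60 (SE 0.38) in the mutant knock-in against the knockout, where 3 rose and 1 fell (4 and 1 adjusted over the list alone). Among smooth muscle markers the potassium channel KCNJ8 changed by -2.52 (SE 0.24) in senescence, 2.11 (SE 0.25) in the knockout and -1.94 (SE 0.26) in the mutant knock-in against the knockout. In the knockout against senescent control 1 of the 4 smooth muscle markers was higher and 1 lower, also adjusted over the list alone. None of these 3 lists passed camera with an estimated correlation in the mutant knock-in against the knockout (edgeR fit, adjusted p = 0.275, 0.308 and 0.459).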
